A study of Homo sapiens with 83 samples.

How the data were processed

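Renal cell carcinoma tissue and plasma cell-free DNA were assayed by ChIP-seq, MeDIP-seq and low-pass whole-genome sequencing. The deposited files were 75 peak lists, 1 per library, for 83 samples, and the 8 tissue input libraries were not analysed here. Each list gives the chromosome, start and end of every peak with a score, which is the authors' own value per peak from their peak caller. The scale of the score is not given in the sources used here, no list held a score below 2.00, and it was used only to rank or filter peaks within a list. Per the submitters' processing notes, MACS (version not given) and bedtools 2.29.2 were used with genome build hg19. Whether an input library served as control, and how reads were filtered, is not given in the sources used here. Peaks were called per library, not on pooled samples. The lists hold no read counts, so depth per sample is unknown, and the number of peaks and the covered length are the only signs of it. The shortest peak of a list can follow depth, library preparation or sequencing.

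Samples were grouped by the histology given in the labels. The 2 plasma H3K4me3 libraries whose own label and plasma number disagree on histology were left out of the groups and entered in each group as alternatives. Nothing was taken from sex chromosomes, and coordinates are hg19 and 1-based. Tests of promoters and gene lists had been planned, but no hg19 gene annotation was used here. Regions of merged peaks took the place of promoters in plasma, and 1 kb windows took their place in the comparison of methylation with active marks. Chromosome bands came from the hg19 band table in the image.

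For the region tests, peaks on the 22 autosomes were merged within a comparison into regions, and regions over 5 kb were split at 5 kb. Merged regions of the tumour marks, of LP-WGS and of recurrent tissue MeDIP were not split. A library had a region when a peak overlapped it by at least 1 bp. Tissue MeDIP regions with a peak in at least 4 and absent from at least 4 libraries were tested, and plasma regions with at least 2 of each, by two-sided Fisher's exact test with Benjamini-Hochberg adjustment and a threshold of 0.05. Named regions were up to 5 in each direction by the lowest adjusted p, then the larger difference, then position, a rule set before the data were examined. Longest, densest and leading H3K27ac and H3K4me2 regions were described after the data were seen.

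Peak number (log2), covered length, share of peaks per arm and share of peaks in tissue-defined regions were compared by two-sided exact permutation tests of the difference of means. Arm shares used 39 arms, leaving out 5 short arms. Paired measures within tumours used two-sided exact sign-flip tests, with the assays of a tumour paired by the tumour number in the labels. Tumour-marked regions were the merged H3K27ac and H3K4me2 peaks of the 8 sarcomatoid tumours, 6.12% of the autosomes. Recurrent tissue MeDIP regions had a peak in at least 10 of the tissue libraries. Shares of plasma peaks in tissue-defined regions were taken over autosomal peaks outside LP-WGS regions, and their p-values were adjusted over 4 tests, also in each alternative. For tissue-defined regions in plasma, at least the 500 regions of lowest p in each direction were taken with ties kept, giving 1247 higher in sarcomatoid and 1043 higher in epithelioid tissue, of which 1247 and 56 had passed the tissue test, and 0.5 was added to each cell of an odds ratio. Random placement used 20000 intervals of 200 bp. P-values measure the spread between the donors sampled.

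The region test was checked on simulated libraries with 200 changed regions. For tissue MeDIP (251923 regions) it recovered 74% of regions present in 2% of one group and 98% of the other, and 0 at 10% and 90% or at 25% and 75%. With 200 changed regions the threshold was stricter than in the real data, where 1303 regions were called. Fisher's exact p-values up to 0.000119 passed there, so these rates do not carry over. For plasma H3K27ac (2683 regions), H3K4me3 (9497 regions) and MeDIP (144303 regions) it recovered 0 at every size, so a count of 0 called regions in plasma has no weight. The arm test recovered 96.7% of simulated changes to 0.7 of the share and 55% of changes to 0.85 over 39 arms. Both simulated groups had the epithelioid spread between tumours, so these rates may be too high where sarcomatoid tumours spread more.

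Alternatives tried were lists of equal length, the better-scored 50% of each list, an overlap of 50%, other filters, and leaving out each library or the libraries of fewer than 1000 peaks. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9.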

Results

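Renal cell carcinoma with sarcomatoid differentiation, in which tumour cells take on a spindle-shaped, mesenchymal appearance, was compared with renal cell carcinoma of epithelioid histology in tumour tissue and in cell-free DNA from plasma. H3K27ac, a histone mark of active promoters and enhancers, and H3K4me2, a mark of promoters and enhancers, were profiled by ChIP-seq in 8 sarcomatoid tumours each. DNA methylation was profiled by methylated DNA immunoprecipitation (MeDIP-seq) in 9 sarcomatoid and 10 epithelioid tumours. In plasma, H3K27ac and MeDIP were measured in 5 sarcomatoid and 5 epithelioid samples each, H3K4me3, a promoter mark, in 3 sarcomatoid and 5 epithelioid samples, and low-pass whole-genome sequencing (LP-WGS) in 5 and 5. A further 2 plasma H3K4me3 libraries carried conflicting histology labels and were kept out of the groups. Of 83 samples, 75 had a peak list, and the 8 tissue inputs were not analysed here. Each list held the peaks of 1 library with the authors' own score per peak, so the read depth behind a peak is unknown and a missing peak cannot be told from low depth.

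Tissue H3K27ac lists held 35252 ± 9974 peaks (SD, n = 8) and tissue H3K4me2 lists 56814 ± 6792. Tissue MeDIP gave the longest lists, with 221598 ± 181850 peaks in sarcomatoid (n = 9) and 188515 ± 39857 in epithelioid tumours (n = 10). Plasma MeDIP lists held 56659 ± 57891 and 83397 ± 26181 peaks, while plasma H3K27ac lists held only 2729 ± 2252 and 2538 ± 1856 (n = 5 each). Plasma H3K4me3 lists held 6878 ± 5120 peaks in sarcomatoid (n = 3) and 6584 ± 4536 in epithelioid samples (n = 5). Peak number did not differ between histologies beyond the spread between libraries in any of the 4 assays tested, nor did covered length (two-sided exact permutation tests, adjusted p from 0.896 to 0.964 over 8 tests). The sarcomatoid tissue MeDIP lists varied more, with an SD of log2 peak number of 1.15 against 0.30.

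**Figure D1:**
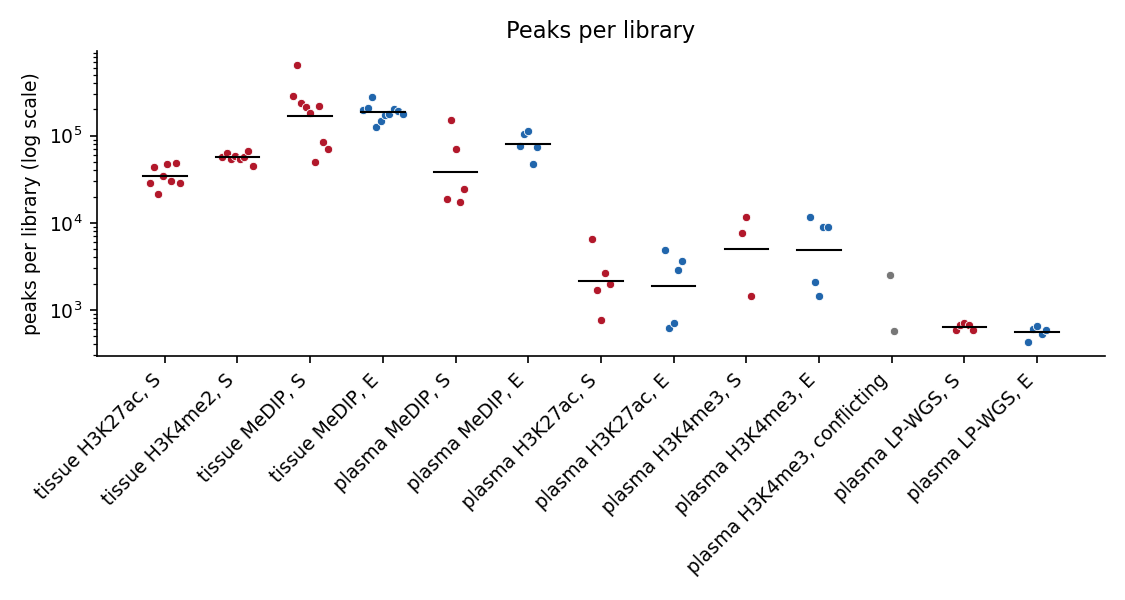
Peaks per library on a log axis for each assay and group, with S for sarcomatoid and E for epithelioid samples. Each point is 1 library and each line the geometric mean of its group, except for the 2 libraries with conflicting labels. Sarcomatoid tissue MeDIP spanned 49565 to 654920 peaks, and epithelioid tissue MeDIP 127422 to 278073.

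The active marks of the 8 sarcomatoid tumours combined a common core with many sites seen in a single tumour. H3K27ac peaks merged into 80515 regions covering 103 Mb, of which 9806 (12.2%) were marked in all 8 tumours and 40068 (49.8%) in 1. H3K4me2 gave 116616 regions over 150 Mb, with 21270 (18.2%) in all 8 tumours and 46916 (40.2%) in 1. The median length was 2522 bp for H3K27ac and 2846 bp for H3K4me2 regions of all 8 tumours, against 420 and 412 bp for regions of a single tumour. A region merged from peaks of more tumours is longer by construction, and a longer region is more likely to overlap the other mark. Of the H3K27ac regions in all 8 tumours, 98.1% also had H3K4me2 in all 8, whereas 41.4% of the H3K27ac regions of a single tumour had H3K4me2 in no tumour.

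H3K27ac regions marked in all 8 tumours, called core regions here, were spread unevenly over the bands. Band 6p21.33, within the major histocompatibility complex, held 24.7 core regions per Mb, 11q13.1 held 24.4, 1q22 held 22, 6p22.2 held 20.6 and 19p13.11 held 20.5, against 3.40 per Mb over the autosomes. The longest core H3K27ac regions lay at chromosome 5, 172275150 to 172320791 (5q35.1, 45.6 kb) and chromosome 11, 65236400 to 65278721 (11q13.1, 42.3 kb), in hg19 coordinates. The next 3 lay in 17q23.1 (35.1 kb), 20q11.21 (32.4 kb) and 20q13.12 (31.9 kb). Ranked by the authors' score within each list, the leading H3K27ac regions were chromosome 5, 132386183 to 132389590 (5q31.1) and chromosome 9, 33023954 to 33027376 (9p21.1), with median ranks in the top 0.0315% and 0.0331% of the lists. Their worst ranks in a single tumour were 11.8% and 7.04%, so they did not lead in every tumour. For H3K4me2 the leading regions lay at chromosome 2, 114339892 to 114343318 (2q13) and chromosome 16, 30216798 to 30218145 (16p11.2).

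Within each tumour most H3K27ac peaks overlapped H3K4me2. On average 78.6% ± 11.1 of H3K27ac peaks overlapped an H3K4me2 peak of the same tumour (SD, n = 8, range 59.9% to 92.8%). Of the H3K4me2 peaks, whose lists were longer, 44.3% ± 11.2 overlapped H3K27ac; the 2 shares depend on the lengths of the lists and were not compared. H3K4me2 covered 34.6 Mb more than H3K27ac (SD 17.4, two-sided exact sign-flip test, p = 0.00781, the smallest possible with 8 tumours) and did so in every tumour. No epithelioid tissue ChIP-seq was used here, so these marks have no histology contrast.

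MeDIP coverage dipped at active sites relative to their flanks within the same sarcomatoid tumour. In 7 tumours with all 3 assays, 1.69% of H3K27ac peak middles were covered by a MeDIP peak, against 3.52% of positions 1 kb away and 4.25% of positions 2 kb away. The log2 ratio of middle to 2 kb was -1.38 (SD 0.47, n = 7, exact sign-flip p = 0.0156, the smallest possible). Around H3K4me2 peaks coverage fell from 4.03% at 2 kb to 2.23% at the middle (log2 -0.78, SD 0.35, n = 7, exact p = 0.0156). The dips of the 2 marks were not tested against each other. MeDIP peaks of these tumours covered 11.7 to 133 Mb of the 2881 Mb of autosomes, a smaller share than of these flanks. The dips are thus relative to flanks rich in MeDIP peaks, and the middles were not tested against the genome.

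Windows of 1 kb with H3K4me2 but no H3K27ac were methylated more often than windows with both marks. A MeDIP peak lay over 16.6% ± 9.26 of windows with H3K4me2 alone, 10.3% ± 7.26 of windows with both marks and 10.9% ± 6.75 of windows with neither (SD, n = 7). Windows with H3K27ac alone ranged from 2.34% to 35.7% between tumours and lay above windows with both marks in all 7 tumours. A higher share than with both marks was thus seen with either mark alone. Windows with H3K27ac alone were not tested against those with both marks or with H3K4me2 alone. The share was lower with both marks than with H3K4me2 alone in all 7 tumours (log2 ratio -0.78, SD 0.23, exact sign-flip p = 0.0156). H3K27ac windows as a whole did not differ from the remaining genome (log2 odds ratio -0.10, SD 0.32, exact p = 0.438), while H3K4me2 windows were more often methylated (0.40, SD 0.16, exact p = 0.0156). The H3K27ac value depended on the overlap asked for: at 50% overlap it was -0.54 (exact p = 0.0313).

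**Figure D2:**
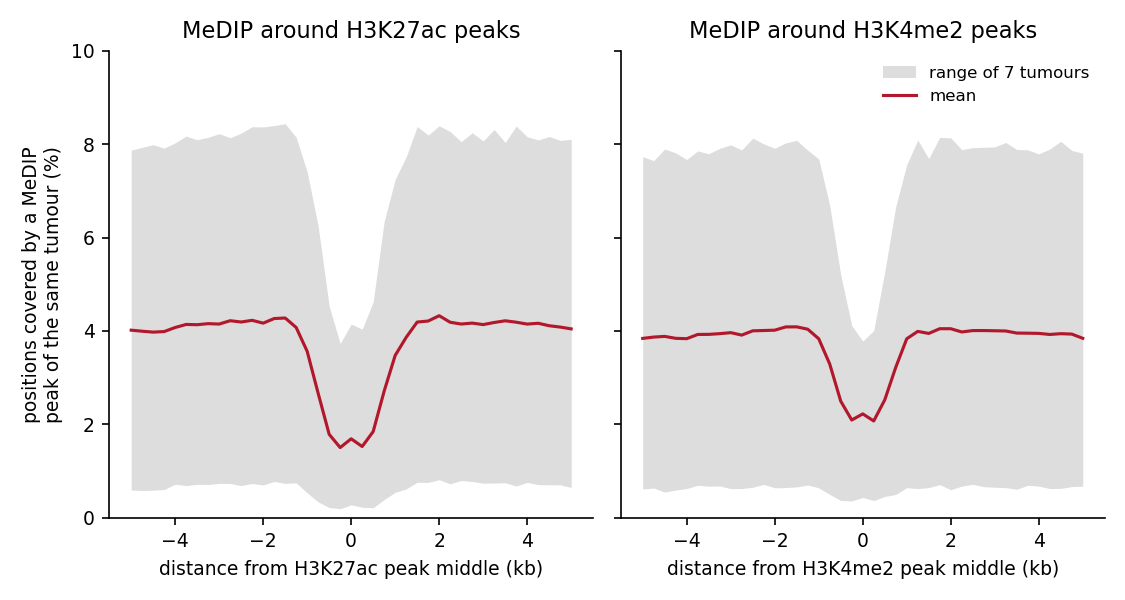
Percentage of positions covered by a MeDIP peak of the same tumour, by distance in kb from the middle of H3K27ac peaks (left) and H3K4me2 peaks (right). The line is the mean of 7 sarcomatoid tumours and the shading their range; coverage fell to 1.69% at H3K27ac middles and 2.23% at H3K4me2 middles.

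MeDIP regions that differed between histologies were mostly higher in sarcomatoid tumours. Of 251923 regions tested, 1247 had a peak in more sarcomatoid tumours and 56 in more epithelioid tumours (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p of 0.05 or less). With lists of equal length the counts were 947 and 381. In 263 regions all 9 sarcomatoid and none of the 10 epithelioid tumours had a peak, and in 6 regions the opposite held. Of the regions higher in sarcomatoid tumours, 2.81% overlapped H3K27ac and 4.41% H3K4me2, both mapped in sarcomatoid tumours only, against 6.50% and 11.0% of all tested regions. They lay within 5 Mb of a centromere in 11.1% of cases, against 7.15% of tested regions. These shares were not tested.

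Among the named regions, those with a peak in 9 of 9 sarcomatoid and 0 of 10 epithelioid tumours lay at chromosome 1, 5715835 to 5716237 (1p36.31), 12927224 to 12927819 (1p36.21), 33536252 to 33536665 (1p35.1), 55285407 to 55285931 (1p32.3) and 64863791 to 64864125 (1p31.3). Regions with a peak in 0 of 9 sarcomatoid and 10 of 10 epithelioid tumours lay at chromosome 4, 136004458 to 136005054 (4q28.3), chromosome 5, 89073431 to 89074212 (5q14.3), chromosome 6, 95467353 to 95468350 (6q16.1), chromosome 9, 9208824 to 9209226 (9p23) and chromosome 15, 30813515 to 30814093 (15q13.2). Each had a Fisher's exact p of 1.08e-05 (adjusted p = 0.0101), the smallest that 9 against 10 tumours allow, and none overlapped H3K27ac or H3K4me2 of a sarcomatoid tumour. Because 263 regions tied at this p, the first 5 were taken by position. Of the bands, 7q11.22 held 17 of the higher regions (5.35 times its share of tested regions), 2p11.2 held 13 (3.97 times), and 10q11.21 (6.14 times) and 19p13.2 (1.62 times) held 11 each, while 5q14.3 held 3 of the lower ones.

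The counts of tissue regions moved with the libraries included. Leaving out any 1 epithelioid library gave 264 to 298 higher and 6 to 9 lower regions. The 879 regions with a peak in 8 of 9 sarcomatoid and 0 of 10 epithelioid tumours cannot pass with 1 epithelioid tumour fewer. This fall in higher regions thus follows group size and not a particular library. The counts rose to 2757 higher without sarcomatoid library 6, 2313 higher without library 9 and 207 lower without library 2. The shortest peak of a list was 65 to 173 bp in sarcomatoid and 190 to 240 bp in epithelioid tissue MeDIP, with no overlap between the histologies.

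Whole chromosome arms differed in their share of tissue MeDIP peaks. Sarcomatoid tumours had a lower share on 9p, the arm of the tumour suppressor CDKN2A, at 0.960% ± 0.254 against 1.37% ± 0.128 of peaks (ratio 0.699, log2 -0.52, exact permutation, adjusted p = 0.00338, 0 of 9 tumours above the epithelioid mean). Shares were also lower on 18q (ratio 0.754, adjusted p = 0.00549, exact permutation, 0 of 9 above), 4q (0.816), 18p (0.824), 9q (0.831), 13q (0.844) and 4p (0.864). Arms 20q (ratio 1.30, adjusted p = 0.00619, exact permutation, 8 of 9 above) and 20p (1.18) had higher shares. In all, 9 of 39 arms passed the test, 7 lower and 2 higher.

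Arm 3p, which carries VHL and is commonly lost in clear cell renal carcinoma, did not differ between histologies (ratio 1.04, exact permutation, adjusted p = 0.799). Arms 17q (ratio 1.19, adjusted p = 0.0895, exact permutation) and 19q (1.14, adjusted p = 0.0684, exact permutation) missed the threshold. On 9p, 2 regions were called higher in sarcomatoid tumours (0.160% of the higher regions) and 4 lower (7.14% of the lower ones). The arm held 1.22% of tested regions, and these shares were not tested. The lower share on 9p held with equal-length lists (log2 -0.89) and within light cytogenetic bands alone (-0.48).

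**Figure D3:**
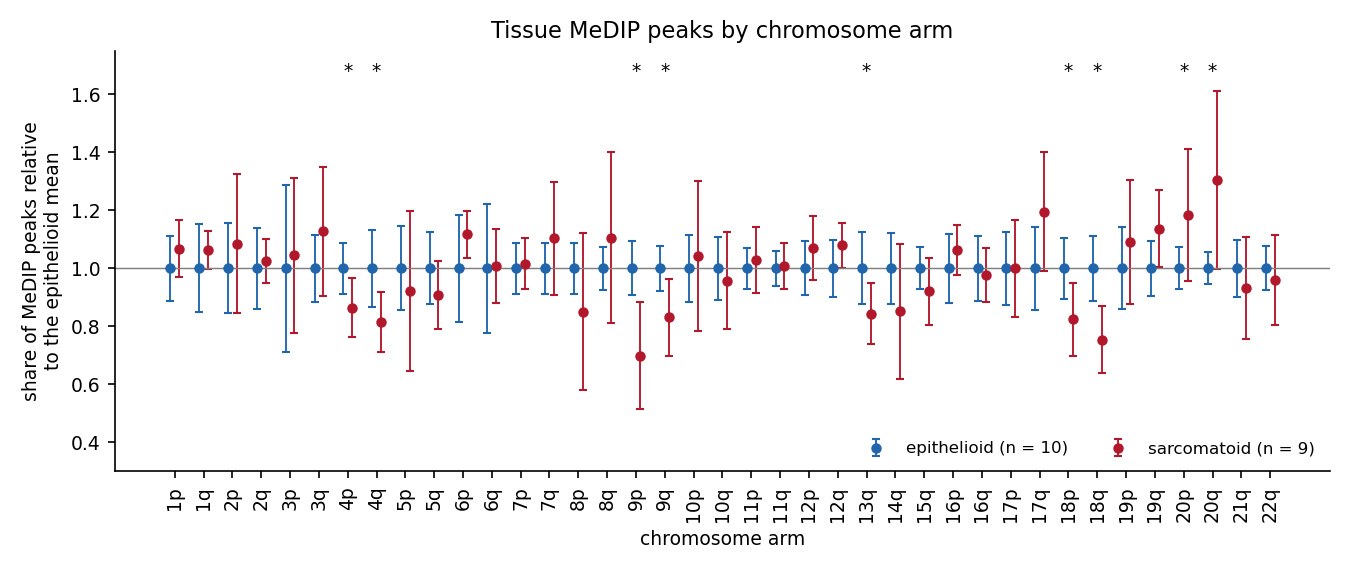
Share of tissue MeDIP peaks on each of 39 chromosome arms, divided by the epithelioid mean of the arm (no unit). Points are group means and bars 1 SD, for 9 sarcomatoid and 10 epithelioid tumours, and asterisks mark the 9 arms with an adjusted p of 0.05 or less, such as 9p at 0.699 and 20q at 1.30.

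Tumour and plasma of the same histology were set side by side by arm; the plasma shares themselves differed between histologies on 16 of 39 arms. Sarcomatoid tumours had lower shares than sarcomatoid plasma on 4p (ratio 0.740), 18q (0.749), 9p (0.764), 9q (0.795), 18p (0.815), 22q (0.819), 21q (0.822) and 13q (0.860). They had higher shares on 3q (1.32), 20p (1.21), 12q (1.20), 12p (1.14) and 1q (1.09), so that 13 of 39 arms passed the exact permutation test at an adjusted p of 0.05. Leaving out 1 library gave 6 (without plasma library 4) to 14 arms. In epithelioid tumours 0 of 39 arms passed, with 5 at an unadjusted exact permutation p under 0.05. Among those 5 were 3p (ratio 0.739, p = 0.0240, adjusted p = 0.234, lower in 9 of 10 tumours) and 5q (ratio 1.15, p = 0.00599, adjusted p = 0.234, higher in 9 of 10). The rest were 19p (ratio 1.21, exact permutation p = 0.0140), 19q (1.14, p = 0.0180) and 20q (1.07, p = 0.0326), with adjusted p of 0.234, 0.234 and 0.255. The sarcomatoid 3p ratio was 0.867 (exact permutation, adjusted p = 0.341).

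For 9p in the sarcomatoid set, the log2 ratio was -0.39 (adjusted p = 0.0390, exact permutation). It was -0.71 with equal-length lists (exact permutation, adjusted p = 0.0917), -0.44 with the better-scored 50% of peaks (0.107) and -0.34 in light bands (0.0682), so the direction held while the call was lost. The call was also lost in 9 of 14 cases when 1 library was left out (exact permutation, adjusted p from 0.0505 to 0.0970), with log2 ratios from -0.45 to -0.29 over all 14. Whether arms differed more in one histology than in the other was not tested.

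Plasma H3K27ac peaks of epithelioid samples lay mostly where tumours are marked, and those of sarcomatoid samples mostly did not. Outside regions that gave peaks in LP-WGS, 71.3% ± 33.2 of epithelioid peaks fell in regions with H3K27ac or H3K4me2 in a tumour, against 15.3% ± 4.99 of sarcomatoid peaks (SD, n = 5 each, two-sided exact permutation p = 0.0159, adjusted p = 0.0476). Randomly placed 200 bp intervals fell there in 7.53% of cases. Epithelioid samples ranged from 19.5% to 95.0% and sarcomatoid samples from 11.5% to 22.6%. Leaving out 1 library gave differences of -69.0 to -50.1 percentage points, but in 8 of 10 cases the call was lost (exact permutation, adjusted p = 0.0635). The tumour-marked regions were defined in sarcomatoid tumours alone. The median H3K27ac peak was 176 to 188 bp long in sarcomatoid and 213 to 300 bp in epithelioid libraries, so peak length separated the same groups. Among H3K27ac sites present in at least 6 tumours, 10.3% ± 9.77 had a peak in an epithelioid and 0.894% ± 0.633 in a sarcomatoid plasma sample.

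At the level of single regions, 0 of 2683 plasma H3K27ac regions passed Fisher's exact test after adjustment, with 88 at an unadjusted p under 0.05, of which 86 were lower in sarcomatoid plasma. The log2 odds ratio of a plasma peak at recurrent against rare tumour H3K27ac sites was 2.70 ± 0.70 in sarcomatoid and 4.96 ± 2.41 in epithelioid samples (difference -2.26, n = 5 each, exact permutation p = 0.103). Recurrent sites are longer by construction, so a positive value is not by itself enrichment, and no set of matched length was compared. Without the libraries of fewer than 1000 peaks, the share differed by -79.1 percentage points, but with 4 against 3 libraries the exact permutation p was 0.0571 (adjusted p = 0.114).

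**Figure D4:**
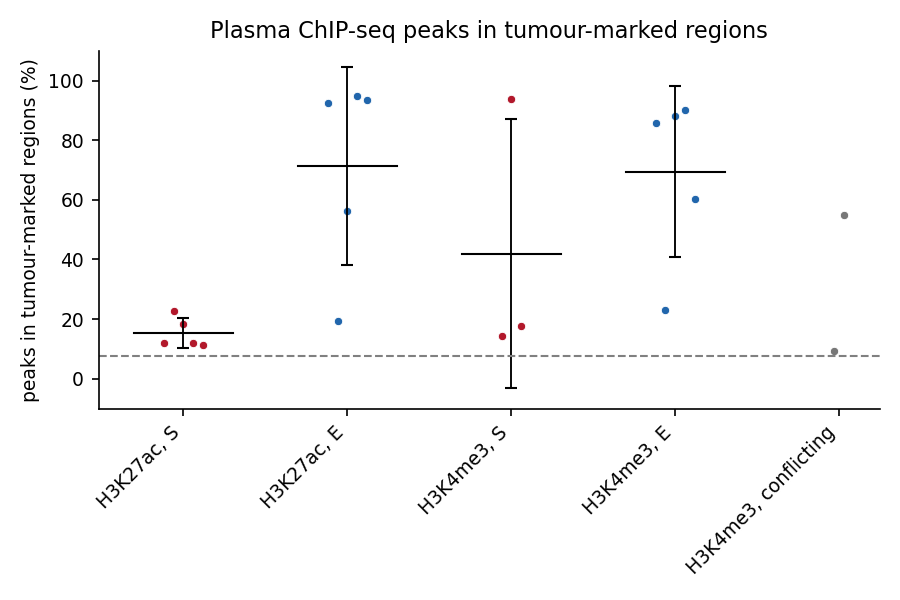
Percentage of plasma H3K27ac and H3K4me3 peaks inside tumour-marked regions, 1 point per library, with S for sarcomatoid and E for epithelioid plasma. Lines are group means and bars 1 SD (no mean is drawn for the 2 libraries with conflicting labels), and the dashed line is random placement at 7.53%; all 5 sarcomatoid H3K27ac libraries lie at or below 22.6%.

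Plasma H3K4me3 peaks did not separate the histologies. In tumour-marked regions lay 41.9% ± 45.1 of sarcomatoid (n = 3) and 69.5% ± 28.6 of epithelioid peaks (n = 5, exact permutation p = 0.357, with 0.0357 the smallest possible). One sarcomatoid library reached 94.0% while the other 2 were at 14.2% and 17.5%, and leaving out 1 library moved the difference of -27.6 percentage points to between -53.6 and -13.7. Of 9497 regions, 0 passed Fisher's exact test after adjustment and 4 had an unadjusted p under 0.05.

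Plasma MeDIP peaks lay in the methylated regions of tumours in both histologies. Regions methylated in at least 10 tissue libraries held 75.2% ± 7.92 of sarcomatoid and 71.0% ± 4.29 of epithelioid plasma peaks (n = 5 each, exact permutation p = 0.333). Randomly placed intervals, not matched for base composition, lay there in 4.46% of cases. No MeDIP of blood or normal tissue was used here, so whether these peaks came from tumour DNA cannot be told. Sarcomatoid plasma MeDIP peaks lay more often in tumour-marked regions, at 13.1% ± 2.58 against 10.5% ± 0.886 (n = 5 each, exact permutation p = 0.0238, adjusted p = 0.0476), with overlapping ranges of 11.2% to 17.6% and 9.57% to 11.7%. The call was lost in 9 of 10 cases when 1 library was left out (exact permutation, adjusted p from 0.0635 to 0.0952), and without sarcomatoid library 5 the difference was 1.44 in place of 2.56 percentage points. Of 144303 regions, 0 passed Fisher's exact test after adjustment and 4851 had an unadjusted p under 0.05, 988 higher and 3863 lower in sarcomatoid plasma.

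By chromosome arm, plasma MeDIP differed on 16 of 39 arms, 9 with a higher and 7 with a lower sarcomatoid share. The largest ratios of sarcomatoid to epithelioid plasma were 1.48 on 19p, 1.28 on 19q, 1.25 on 22q and 1.22 on 16p. Lower shares were found on 3q (0.857), 4q (0.889), 3p (0.890), 5q (0.903) and 9p (0.908). Each of these arms had an adjusted p of 0.0206 (exact permutation, 5 of 5 sarcomatoid libraries on the same side of the epithelioid mean), the value given by the smallest p of 5 against 5. Causes of these differences, base composition among them, were not tested.

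Tissue MeDIP regions with the lowest p in each direction were looked for in plasma MeDIP. All 1247 regions higher in sarcomatoid tumours had passed the tissue test, but only 56 of the 1043 higher in epithelioid tumours. The regions higher in sarcomatoid tumours had a peak in 14.4% ± 6.18 of cases in sarcomatoid and 23.2% ± 10.9 in epithelioid plasma. Those higher in epithelioid tumours had one in 11.8% ± 15.7 and 17.0% ± 6.55. The log2 odds ratio between the sets was 1.16 ± 1.95 in sarcomatoid and 0.56 ± 0.65 in epithelioid plasma, a difference of 0.60 within the spread between libraries (n = 5 each, exact permutation p = 0.532). Leaving out sarcomatoid plasma library 2 raised the difference to 1.40 (exact permutation p = 0.0317).

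LP-WGS, sequenced without immunoprecipitation, gave short peak lists that gathered near centromeres. The 10 libraries held 425 to 705 peaks, which merged into 930 regions, 284 of them present in all 10 libraries. Of these regions 57.8% lay within 5 Mb of a centromere, a zone that makes up 11.0% of the autosomes. Sarcomatoid samples had a log2 peak number higher by 0.22 (exact permutation, adjusted p = 0.0952) and covered 0.0176 Mb more (exact permutation, adjusted p = 0.0952), neither past the threshold. Of 22 autosomes, 0 passed the exact permutation test after adjustment, and chromosomes 6 and 11 had an unadjusted p under 0.05. The smallest p of 5 against 5, 0.00794, adjusts to 0.175 when 1 of 22 chromosomes reaches it, so a single chromosome could not pass.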

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

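Of the tests weighed here, those of list length, regions shared with LP-WGS, library preparation, base composition, copy number, DNA quality and the splits of plasma MeDIP arms were chosen after the result was seen. Of 49 pairs of group and measure examined for a library far from the rest of its group, 7 stood apart, where chance gives about 1 in 20. Sarcomatoid tissue MeDIP library 2 held 654920 peaks. Epithelioid tissue MeDIP library 4 had 0.366% of its peaks over LP-WGS regions, and library 2 had 14.8% in tumour-marked regions. Sarcomatoid plasma H3K27ac library 3 had 47.5% of its peaks over LP-WGS regions. Epithelioid plasma MeDIP library 1 had a median peak of 237 bp. Sarcomatoid plasma MeDIP library 5 had a median peak of 306 bp and 17.6% of its peaks in tumour-marked regions.

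MeDIP regions higher in sarcomatoid tumours outnumbered lower ones. Neither list length nor regions that give peaks without immunoprecipitation accounts for all of it. The ratio fell but was still 2.49 with equal-length lists, and 2.17% of the higher regions overlapped LP-WGS peaks. Of all tested regions 0.0798% did so, and of the lower ones 0%. Such regions were thus over-represented among the higher regions but made up a small part of them. Chance is unlikely, as 1 of 100 splits of the tumours, the real one, gave 1303 called regions and the highest other gave 0. A difference in depth, library preparation or sequencing cannot be told apart from histology, because the shortest peaks of the groups were separated by a gap of 17 bp, with no library of one group in the range of the other. A biological difference between the histologies stays open beside it, untested.

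Whether the arm shares of tissue MeDIP that differed between histologies reflect DNA copy number of the tumours stays open. List length does not account for the 9p difference, whose ratio was 0.539 with equal-length lists. In light bands the ratio was 0.718. Light bands of different arms can still differ in base composition, so this value cannot decide on base composition, which stays open. Arm profiles were log2 shares of 7 sarcomatoid tumours, with the mean of these tumours subtracted for each arm. The subtraction by itself pushes correlations with other tumours below 0, so those values are no independent contrast. The H3K4me2 profile of a tumour correlated with its own MeDIP profile at a mean r of 0.72, against -0.12 with other tumours. Arms are not independent replicates. In 7 of 7 tumours the own profile was the best match (one-sided exact pairing p = 0.000198, the smallest possible). For H3K27ac the mean r with the own MeDIP profile was 0.53 (lowest 0.22, other tumours -0.083) and with the own H3K4me2 profile 0.73 (lowest 0.27, other tumours -0.12), with 6 of 7 tumours matched best in each (both exact pairing p = 0.000198). As 1 of 100 splits gave 9 called arms, with 3 the highest other, chance is unlikely, though arm shares were added after the data were seen. The matched profiles held no epithelioid tumour, and any arm shift common to the sarcomatoid tumours had been subtracted. They show arm differences between sarcomatoid tumours that the marks share, and cannot decide on copy number for the difference between histologies. For that difference, the separated shortest peaks also leave depth, preparation or sequencing open, and no copy-number call was made.

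Plasma H3K27ac peaks of the sarcomatoid group lay less often in tumour-marked regions. The difference was -47.2 percentage points with equal-length lists, -43.4 with LP-WGS regions kept and -56.0, as reported, with them left out, so neither list length nor those regions account for it. MeDIP of the same samples differed by 4.21 percentage points in recurrent tissue MeDIP regions, and by -2.48 with equal-length lists. MeDIP does not need histone-bound DNA and cannot speak for the material that ChIP needs, so poor plasma samples stay open. Of the sarcomatoid peaks outside tumour-marked regions, 1.16% recurred in another library of the group (0.557% to 4.93% per library). In the epithelioid group 20.4% recurred (13.3% to 39.2% per library). Sarcomatoid lists had a peak at only 0.894% ± 0.633 of H3K27ac sites found in at least 6 tumours, so shared sites could also seldom recur. No rate of random overlap was taken. Other sites shared between sarcomatoid plasma samples thus stay open. Peak length separated the groups as well (medians of 176 to 188 and 213 to 300 bp), so weaker immunoprecipitation or another difference in preparation stays open, as does a biological difference; none was tested.

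Splits of the samples gave these further counts. For plasma regions and LP-WGS chromosomes the real count was 0 and the highest other 0, so that all splits (100 of 100 for H3K27ac, MeDIP and LP-WGS, 56 of 56 for H3K4me3) gave as many by construction, which says nothing about chance. For plasma MeDIP arms 1 of 100 splits, the real one, reached 16 called arms, and the highest other reached 0. For sarcomatoid tissue against plasma 1 of 100 splits reached 13 arms, with 5 the highest other. Chance is unlikely for both, but 100 splits cannot show a rate under 1 in 100, and arm shares were added after the data were seen. With 5 against 5 plasma samples, arms could pass only if several reached the smallest p together, so 0 in the other splits is weak evidence. For epithelioid tissue against plasma the real split gave 0 and the highest other 1, and 100 of 100 gave as many, again by construction.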

How the results depend on the processing

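Arm shares, shares of peaks in tissue-defined regions, tissue libraries within the epithelioid range of peak numbers, windows with MeDIP elsewhere and regions without LP-WGS overlap were added after seeing the data. Of 584 alternatives over 39 results, 487 kept direction and threshold side, or a call count near the main one or at 0. Another 60 were weaker, 19 stronger and 18 reversed. Plasma region counts of 0 have no weight. Causes were not tested except where fewer libraries were compared. Histologies came from different donors and could not be paired. Promoter windows, gene filters, gene lists and, for LP-WGS, medians and other thresholds were not run.

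Without libraries of fewer than 1000 peaks, the log2 difference in plasma H3K27ac peak number was -0.42 and the share in tumour-marked regions differed by -79.1 percentage points (exact permutation, adjusted p = 0.114). That share differed by -47.8 with the better-scored 50% of peaks (0.0794) and -43.4 with LP-WGS regions kept (0.0635), and that of plasma MeDIP by 2.83 (0.0794) and 2.51 (0.0635), so these calls were lost. With the conflicting H3K4me3 libraries as sarcomatoid, peak number differed by -0.78 (log2) and covered length by -0.597 Mb. Tissue MeDIP regions lower in sarcomatoid tumours numbered 381 with equal-length lists, beside 947 higher. The better-scored 50% of peaks gave 551 higher. With the 4 sarcomatoid libraries inside the epithelioid range of peak numbers there were 4094 higher and 109 lower. The log2 odds ratio of methylation was 0.40 for H3K4me2 in place of H3K27ac, -0.54 at 50% overlap and -0.49 in windows with MeDIP elsewhere. Equal-length lists gave -2.48 percentage points for plasma MeDIP in recurrent tissue regions.

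Leaving out each library gave these ranges. Tissue MeDIP peak number ran from -0.38 to 0.089 (log2), plasma H3K27ac from -0.20 to 0.57 and H3K4me3 from -0.56 to 0.95, with H3K4me3 covered length from -1.17 to 1.12 Mb. Covered length ran from -19.9 to -4.74 Mb in tissue MeDIP, -11.2 to -3.43 in plasma MeDIP and -0.434 to -0.0656 in plasma H3K27ac. The plasma H3K4me3 share in tumour-marked regions ran from -53.6 to -13.7 percentage points, and sarcomatoid 3p against plasma from -0.27 to -0.12 (log2). Tissue regions higher in sarcomatoid tumours ranged from 264 to 2757 (without sarcomatoid library 6), with 2313 without library 9 and 264 to 298 without any 1 of epithelioid libraries 1 to 10. Lower regions ranged from 6 to 207, with 97, 207 and 102 without sarcomatoid libraries 1, 2 and 3, and 6 to 9 without any 1 epithelioid library. Tissue-defined regions in plasma ranged from 0.071 to 1.40 (log2, 1.40 without sarcomatoid library 2) and tumour H3K27ac sites from -3.16 (without epithelioid library 2, exact permutation p = 0.0317) to -1.79. LP-WGS peak number ran from 0.12 to 0.27 (log2) and covered length from 0.0117 to 0.0223 Mb; without sarcomatoid library 1 both passed (adjusted exact permutation p = 0.0476), as did covered length without epithelioid library 3 (0.0317). The 3p difference between histologies ran from -0.00076 to 0.18 (log2). Called arms ranged from 0 to 1 for epithelioid tissue against plasma (1 without tissue library 4 or 9) and from 6 to 14 for sarcomatoid tissue against plasma (8 without tissue library 5 or 8, 7 without plasma library 2 or 3, 6 without plasma library 4). Plasma MeDIP in recurrent tissue regions ran from 2.31 to 7.38 percentage points and in tumour-marked regions from 1.44 (without sarcomatoid library 5) to 3.04, where only leaving out sarcomatoid library 4 kept the call. Plasma H3K27ac ran from -69.0 to -50.1, where only leaving out sarcomatoid or epithelioid library 2 kept it.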

Other observations

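The plasma H3K4me3 libraries with conflicting histology labels differed from each other. The first held 2486 peaks and the second 576, and 9.35% and 75.5% of their autosomal peaks lay over LP-WGS regions. Of the peaks outside LP-WGS regions, 9.19% and 54.8% lay in tumour-marked regions.

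Within plasma samples that had both marks and agreeing labels, the share of peaks outside LP-WGS regions that lay in tumour-marked regions was not systematically higher for either mark. H3K4me3 minus H3K27ac averaged 7.98 percentage points (SD 31.1, n = 8, two-sided exact sign-flip p = 0.641), with H3K4me3 higher in 4 of 8 samples. Sarcomatoid plasma 2 stood at 94.0% for H3K4me3 and 22.6% for H3K27ac.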
